A study of Mus musculus with 4 samples.

How the data were processed

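ATAC-seq libraries of dermal fibroblasts from C57BL/6 mice were analysed: a Sod2+/+ control, a conditional Sod2 knockout (Sod2-/-), vehicle-treated Sod2+/+ cells and rotenone-treated Sod2+/+ cells, with 1 library per group. The rotenone dose and its unit were taken from the labels and were not checked by the data. Per the labels' protocols, nuclei were isolated by detergent lysis, tagmented with Tn5 transposase, amplified by PCR with dual barcodes and sequenced as paired ends on an Illumina NextSeq instrument. The submitters' processing notes name Bowtie2, bedtools, MACS2 and HOMER and the mouse build mm10; versions, settings, read filters and any shift of reads for the Tn5 insertion site are not given in the sources used here.

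The authors deposited 1 peak list per library with no header, called separately for each library. Its columns hold a position, a name, a score, a fold enrichment and 2 significance values. The deposited score followed the −log10 q in all but 23 peaks in control, 31 in the knockout, 14 in vehicle and 22 in rotenone, and was not used. The fold enrichment is a ratio over the local background as the authors' peak caller gave it, read here in the column order of MACS2 broad peaks. The −log10 p and −log10 q were also the authors' own values; the lowest −log10 q in each list was just above 1, so the lists reach down to a q of 0.1 and hold many weak peaks. These values belong to the single peak and were used only to describe, rank or filter peaks within the same list. Read counts per peak were not used here and depth is unknown, so the lists cannot show how deeply each library was sequenced.

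Coordinates were converted from the 0-based starts of the lists to 1-based mm10 positions. In each list the 30000 peaks with the highest −log10 p (ties by fold enrichment) were called strong. In the definition written before the data were examined, a strong peak was gained (lost) when no peak of any strength in the partner library overlapped it by 1 bp. Because few regions met it, a second definition was chosen after seeing the data: a strong peak that overlapped none of the partner's 60000 highest ranked peaks. The knockout was compared with the Sod2+/+ control and rotenone with vehicle. Vehicle against the Sod2+/+ control gave the size of difference between libraries that differ in neither Sod2 nor rotenone, although they may differ in preparation. Sharing between comparisons was counted on the merged strong regions of the 4 libraries and set against the number for independent sets. Shares have 95% Wilson intervals, which cover counting error only.

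Gene positions came from the RefSeq gene table of GRCm38.p6, the assembly behind mm10, with 21887 protein-coding genes. Gene strand and exons were not used here, so transcription start sites, promoters, exons, introns and UTRs are not told apart. In place of the planned promoter share, the share of peaks within 1000 bp of either end of a gene is given, and in place of the nearest start site, a peak was assigned to the protein-coding gene that spans its midpoint or otherwise to the gene with the nearest end. As a check of the coordinates, 24.4% to 24.9% of strong peaks lay within 1000 bp of a gene end, against 4.66% to 4.89% after a shift of 100000 bp. The planned search for AP-1 motifs was not run, since no genome sequence was used here.

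The 15 gene lists and 8 lists of cell type markers were written before the data were examined, and 411 of 413 members matched the table (Mx1 did not match, and Hprt1 is an older name of Hprt). For each list, gained minus lost regions were placed as a percentile among 10000 random lists of the same size matched on peaks per gene in 20 strata. The matching counted all peaks of the authors' lists, not only the strong peaks that can be gained or lost. For genes rich in strong peaks the range of the random lists may therefore be too narrow. The genes named come from, per comparison and definition, the 10 with most gained and the 10 with most lost regions, the 5 best ranked gained and lost gene end peaks, Sod2, Junb, Jun, Jund, Fos, Fosl1, Fosl2, Igf1, Cdkn2a and Cdkn1a, and up to 3 members per list with the largest net, leaving out predicted and uncharacterised genes. In the knockout Jdp2, Txnrd1, Lox, Lum and Tbx18, and the regions named as shared between comparisons, were picked as examples after their values were seen. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

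The overlap code was tested on simulated changes in the real lists, and 200 of 200 planted regions were recovered in each direction and comparison. Of simulated gene lists with no planted change, 47 of 50 fell inside the middle 95% of random lists, and 48 of 50 with planted gains rose above it. Alternatives were lists of 15000 and 60000, ranking by fold enrichment, 50% of a peak covered, the stronger 50% of the partner list, autosomes only, a gene end window of 2500 bp and genes within 50000 bp. Added after seeing the data were a partner list shortened to 340240 peaks, a minimum fold of 3, a partner peak within 250 bp and assignment by nearest gene end. With 1 library per group no replicate could be left out.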

Results

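Open chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in dermal fibroblasts of C57BL/6 mice. The 4 libraries formed 2 comparisons with 1 library per group. In the first, fibroblasts with a conditional knockout of Sod2 (Sod2-/-), the gene of the mitochondrial manganese superoxide dismutase, were set against Sod2+/+ control fibroblasts. In the second, Sod2+/+ fibroblasts given rotenone, an inhibitor of respiratory complex I labelled at 250 µM, were set against vehicle-treated Sod2+/+ fibroblasts. The labels give 100 days for all 4 samples and do not say what the days count. The title of the series names persistent JunB activity in fibroblasts, the stem cell niche and skin aging, so the comparisons ask how chromatin accessibility differs when mitochondrial superoxide handling or complex I is disturbed.

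The authors' peak lists held 433013 peaks in the Sod2+/+ control, 585165 in the knockout, 340240 in vehicle and 347438 in rotenone. Read depth per library is unknown. Each list was therefore reduced to its 30000 strongest peaks by the authors' −log10 p, so that equally many strong peaks were compared from each library. With no second library in any group, the differences below have no replicate check, no p-value is given, and intervals cover counting error only. The median fold enrichment of the 30000 peaks was 6.78 in control, 5.49 in the knockout, 7.13 in vehicle and 5.99 in rotenone, and their median width was 376, 293, 349 and 277 bp.

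Sod2 itself (chromosome 17, 13007839-13018119, mm10) had a strong peak over 1 gene end in every library, with a fold enrichment of 7.04 in control, 6.67 in the knockout, 7.54 in vehicle and 7.29 in rotenone. A second peak inside the gene, at 13009946-13010245, was among the 30000 strongest in control (fold 4.18) and vehicle (fold 4.47). Its counterparts in the knockout (fold 3.12) and rotenone (fold 3.88) lay below that list and inside the 60000 strongest. The labels do not say which part of Sod2 was deleted, so these peaks do not check the genotype.

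Junb, which encodes the AP-1 subunit named in the title, showed the same 3 strong peaks at its locus (gene at chromosome 8, 84976909-84978748) in all 4 libraries. The peak over its gene end had a fold of 4.16 in control, 4.16 in the knockout, 4.14 in vehicle and 4.24 in rotenone. Inside the gene or within 1000 bp of it, the related AP-1 genes also held equal numbers of strong peaks in each library: 2 at Jun, 1 at Jund, 1 at Fos, 1 at Fosl2 and 0 at Fosl1. Igf1, the gene of a growth factor that dermal fibroblasts secrete, had a strong peak at chromosome 10, 87879959-87880460 in control, overlapped by a strong peak in each other library. Its fold was 7.17 in control, 6.81 in the knockout, 7.04 in vehicle and 9.51 in rotenone. A second Igf1 peak, at 87926930-87927546, was strong in control (fold 5.25) and rotenone (fold 4.70). It lay below the 30000 strongest in the knockout (fold 4.07) and vehicle (fold 5.14). Cdkn2a, which encodes the cell cycle inhibitors p16Ink4a and p19Arf, held 2 strong peaks in control (folds 5.49 and 7.07) and 2 in vehicle (folds 5.64 and 6.71), at chromosome 4, 89276151-89276426 and around its gene end near 89294619, and 0 in the knockout and in rotenone. Weaker peaks remained at both places, with folds of 3.92 and 3.84 in the knockout and of up to 4.51 in rotenone, each place with a peak among the 60000 strongest, so Cdkn2a was not counted as lost under either definition used below. At Cdkn1a, which encodes the inhibitor p21, a strong peak inside the gene was seen in all 4 libraries, with folds of 6.38 in control, 6.84 in the knockout, 7.22 in vehicle and 7.28 in rotenone. A second one, at chromosome 17, 29093613-29093837, was strong in vehicle (fold 6.16) and counted as lost in rotenone under the second definition used below, although a weaker rotenone peak remained there (fold 3.55) and the control peak (fold 4.89) was not among the 30000 strongest either.

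**Figure D1:**
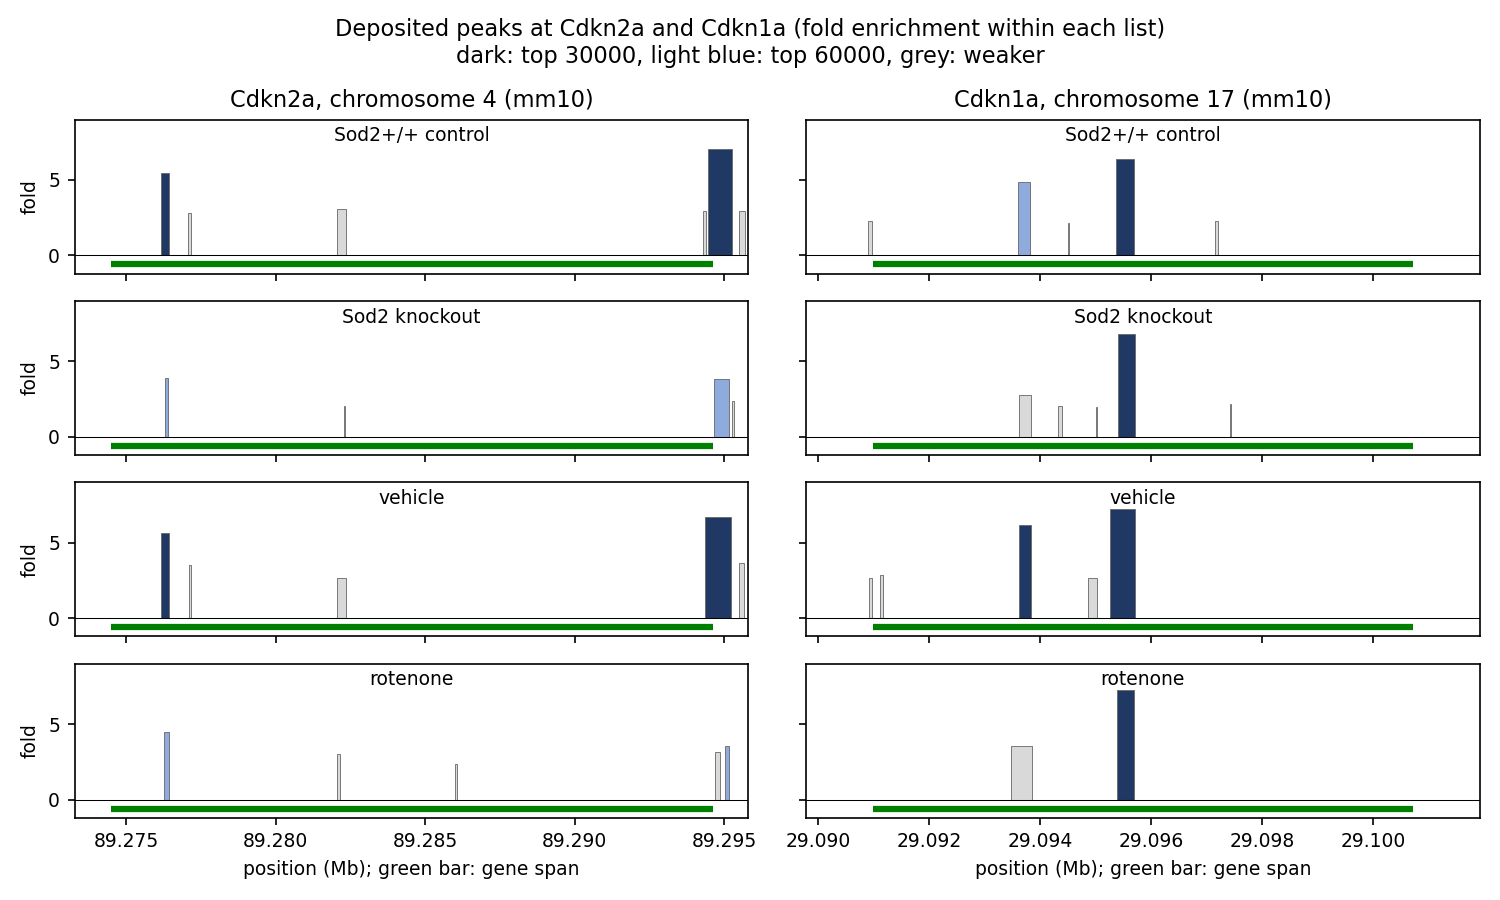
Peaks in the authors' lists at Cdkn2a (left) and Cdkn1a (right) in the 4 libraries, with mm10 position in Mb on the x axis, fold enrichment on the y axis and the gene span as a green bar. Dark bars are among the 30000 strongest peaks of their library, light blue bars among the 60000 strongest and grey bars weaker; Cdkn2a has 2 dark bars in control and in vehicle and 0 in the knockout and in rotenone.

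The knockout and the rotenone library shared more strong regions with each other than with their own controls. Of the 30000 strongest knockout peaks, 82.5% (95% Wilson interval 82.1-82.9) overlapped a strong rotenone peak and 77.2% (76.8-77.7) a strong peak of the Sod2+/+ control. Of the rotenone peaks, 82.0% (81.6-82.4) overlapped the knockout list and 75.6% (75.2-76.1) the vehicle list. The control and vehicle lists overlapped by 85.9% in both directions. The order held under every alternative list length, ranking, overlap rule and chromosome set tried.

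**Figure D2:**
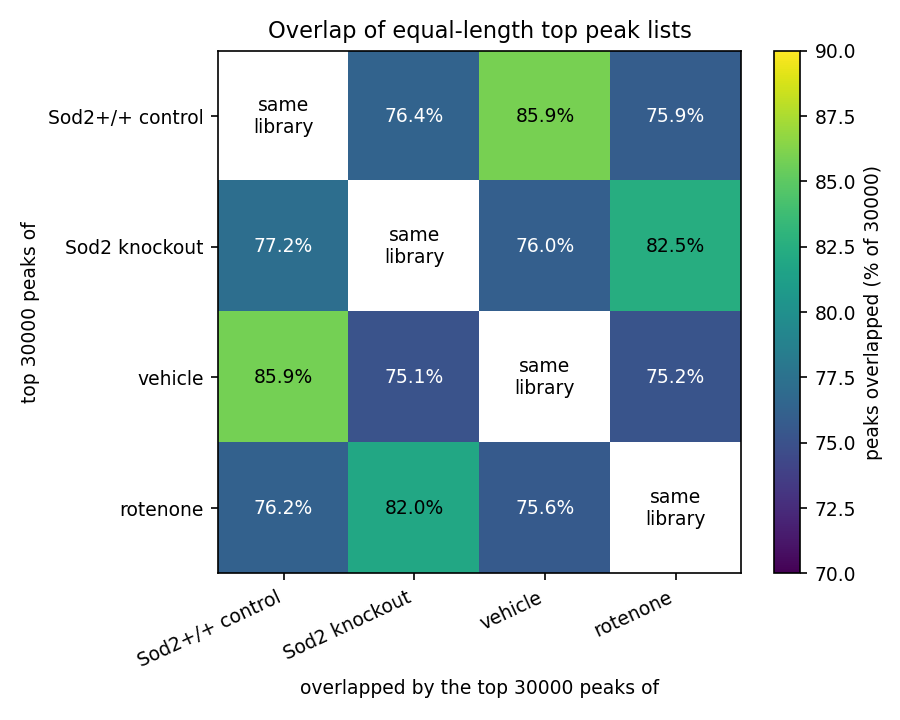
Share of the 30000 strongest peaks of each library (vertical axis) that overlap the 30000 strongest peaks of each other library (horizontal axis), in percent, by colour and number. The pairs control with vehicle (85.9%) and knockout with rotenone (82.5% and 82.0%) stand above the other pairs (75.1% to 77.2%).

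Regions were compared under 2 definitions. Under the stricter one, fixed before the data were examined, a region was strong in 1 library and overlapped no peak of any strength in its partner. This left few regions, and a second definition was chosen after seeing that. Under it, a region was called gained or lost when it was among the 30000 strongest peaks of 1 library and overlapped none of the 60000 strongest peaks of the partner. Each region was assigned to the protein-coding gene that spans it or, outside genes, to the gene with the nearest end. Counts per gene were not adjusted for gene length or number of peaks, so long genes and genes with many peaks can lead by size alone.

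In the Sod2 knockout, strong regions assigned to Lrig3, Grb14 and Lrig1 were lost and regions assigned to Hs6st1, Eef2, Fndc3b and the gene end of Thbs1 gained. Lrig3 and Grb14, which encode a transmembrane leucine-rich repeat protein and an adaptor that inhibits the insulin receptor, lost 5 regions each with 0 gained; for Lrig3, 2 lay inside the gene and 3 at 67402 to 296673 bp from it, and for Grb14, 3 lay inside and 2 at 330023 and 377951 bp. Lrig1, a negative regulator of EGF receptor signalling and a marker of papillary fibroblasts, lost 4. The best ranked, at chromosome 6, 94805556-94805973, lay 105467 bp from the gene, and those at 94627944-94628483 and 94640277-94640659 lay inside it. The secreted factor gene Prok2 and Krr1, a ribosome assembly factor, also lost 4 each with 0 gained, the best ranked at 161736 and 10123 bp from the gene. Celf2 and Msi2, which encode RNA-binding proteins, lost 4 and gained 3 each. Nsmce2, the gene of a SUMO ligase of the SMC5/6 complex, lost 4 and gained 1, and the corepressor gene Ctbp2 lost 4 and gained 2.

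Hs6st1, which encodes a heparan sulfate sulfotransferase, gained 4 regions, all outside genes, the strongest at chromosome 1, 35904114-35904314 (fold 5.77 in the knockout). Eef2, the gene of a translation elongation factor, gained 4 at or inside the gene, with folds of 3.28 to 3.66, and Fndc3b gained 4. Immp2l, which encodes a subunit of a mitochondrial inner membrane peptidase, gained 4 and lost 1, and its strongest region lay 936114 bp from the gene. Zfp825 gained 3, and Ahctf1, which encodes a nuclear pore protein, and Ppp1r14bl gained 3 and lost 1 each. Pisd (5 gained, 1 lost), Scaf8 (4 gained) and Sfi1 (3 gained, 1 lost) also stood among the 10 genes with most gained regions, but these regions had a median fold of 2.85 over the 2 comparisons, below most strong peaks. The best ranked gained gene end peaks fell to Gamt, Heatr9, Tmem211, Actn4 and Thbs1. Of these, Actn4, an actin crosslinker (chromosome 7, 28962171-28962652, fold 7.01), and Thbs1, the gene of the matricellular protein thrombospondin 1 (chromosome 2, 118126995-118127776, fold 4.32), were wider than 400 bp, while the Gamt peak spanned 17 bp and those of Heatr9 and Tmem211 were strong in vehicle too. The best ranked lost ones fell to Fkbp2, Rsph4a, Zw10, Ccnb1ip1 and Maats1. Fkbp2 and Zw10 had folds of 1.93 and 1.94 and were also missing from the vehicle library, while Rsph4a, a radial spoke protein gene, had a fold of 9.43 in control.

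In numbers, 1600 regions were gained and 2027 lost in the knockout, assigned to 1399 and 1736 genes. Vehicle against control, libraries that differ in neither Sod2 nor rotenone, gave 309 and 254. Both of these libraries were more enriched than the knockout and rotenone libraries. Their comparison therefore does not show how many regions a difference in enrichment alone would give. The stricter definition gave 73 gained and 103 lost regions, against 33 and 26 for vehicle against control. Among the stricter set were Pde3a, a phosphodiesterase gene that lost 2 regions, and Nr3c2, Sema5b and Tnks, which gained 1 each. The counts depended on list length and on the overlap rule. With lists of 15000, 735 regions were gained and 837 lost (5 and 14 under the stricter definition). Vehicle against control then gave 144 and 95 (12 and 11). At this length the stricter counts of the knockout were thus no clear excess over those between the control libraries. However, the stricter definition searches the whole partner list, and these lists differ in length. Losses were sought among 585165 knockout peaks, but peaks only in control or only in vehicle among 340240 and 433013. With strong lists of 30000 and partner lists shortened to 340240, 91 regions were gained and 193 lost, against 34 only in vehicle and 26 only in control. With lists of 60000, 7256 regions were gained and 8423 lost in the knockout (2839 and 2004). When a peak counted as shared only with 50% of it covered, 1727 were gained and 3974 lost (287 and 1559), a larger excess of losses. Strong control peaks were wider than those of the knockout (median 376 against 293 bp), and a wide peak is harder to cover by 50%. The larger excess may therefore follow from peak width and is no separate sign of loss.

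Among the gene lists fixed beforehand, only the AP-1 subunits had a net outside the middle 95% of random lists in the knockout, under the second definition. Their genes gained 2 regions and lost 6, a net of -4 that lay at percentile 1.28 of 10000 random gene lists matched on peaks per gene (middle 95%, -3 to 2). The matching used peaks of any strength. In control a larger share of the peaks at these genes was strong than in the whole list, so the range may be too narrow for them. Under the stricter definition these genes gained 0 and lost 0. Fosb lost 2, including chromosome 7, 19308177-19308368 inside the gene (fold 5.58 in control), and Fosl2 lost 1. Jun lost 2 and gained 1 at 40535 to 85572 bp from the gene, the gained one being strong in vehicle too, Jdp2 lost 1 and gained 1, and the other 9 members had neither. With lists of 60000 the net was 1, so its direction depended on list length. A strong gene end peak was present at 7 of the 13 members in control, 9 in the knockout, 8 in vehicle and 9 in rotenone, and one of any strength at 11, 12, 11 and 11. The 26 fibroblast identity genes gained 4 and lost 11 (net -7, percentile 3.89, inside the middle 95% of -8 to 5). Lrig1 accounted for 4 of the losses, 7 members had losses only, among them Cd34 and Tbx18, and Dlk1 was among the 3 with gains only. Of these 26 genes, 11 had a strong gene end peak in control, 6 in the knockout, 9 in vehicle and 8 in rotenone, and 24, 24, 25 and 23 had one of any strength. The knockout peaks were less enriched and narrower as a whole, as given above.

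Collagen and matrix genes gained 12 regions and lost 7, a net of 5 inside the middle 95% of the random lists (-9 to 6). Gains only were seen at 9 of 28 members, including Col12a1 with 2, Lox, a collagen crosslinking enzyme, and Lum, and losses only at 3, including Col1a2 with 2; Col4a1 gained 1 and lost 2. This net turned to -4 with lists of 15000 and to -13 with lists of 60000. Myofibroblast genes gained 3 and lost 1 (percentile 93.2), with 2 gains at the tropomyosin gene Tpm1, 1 of them at a gene end, on chromosome 9, 67049141-67049628. Antioxidant defence genes gained 1 and lost 4 (percentile 12.1). The losses were 2 at Gsr, the glutathione reductase gene, 1 of them at a gene end, on chromosome 8, 33653355-33653629 (fold 7.82 in control), 1 at Nfe2l2, which encodes the antioxidant regulator NRF2, and 1 at Txnrd1, a thioredoxin reductase gene; the gain was at the cystine transporter gene Slc7a11. Growth factor and niche genes gained 8 and lost 11 (percentile 29.6), with 2 gains at the Notch ligand gene Jag1 and 2 losses each at Notch2 and at Smad3, a mediator of TGF-β signalling. Genes of the integrated and mitochondrial stress response lost 2, at Asns and Eif2ak3, and gained 0 (percentile 17.8).

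The other lists lay well inside the range of random lists in the knockout. The IGF axis gained 4 and lost 2 (percentile 81.3), with gains at Insr and Irs1 and a loss at Foxo1. Senescence genes gained 1, at Cdkn2b, and lost 4, including Ccng1 and Cdkn1b (percentile 11.4), and secreted factors of senescent cells gained 1 and lost 3, at Ccl2, Cxcl12 and Mmp2 (percentile 26.0). Proliferation genes gained 4 and lost 3 (percentile 75.5), all 3 losses at Myc. Complex I genes gained 1 and lost 2 (percentile 26.0), glycolysis and hypoxia genes 1 and 1 (percentile 58.8), interferon and NF-kB genes 1 and 2 (percentile 32.5) and housekeeping genes 0 and 1 (percentile 28.9). Markers of other skin cells also stayed inside the middle 95%: the net was -2 for keratinocytes, -1 for endothelial cells, -1 for myeloid cells, 1 for melanocytes and Schwann cells, and 0 for lymphocytes, adipocytes, skeletal muscle and pericytes. By the stricter definition each list had at most 1 changed region, such as a gain near Eln, the elastin gene, and losses near Ccng1 and Ddx58, and 0 of the 23 lists left the middle 95%.

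**Figure D3:**
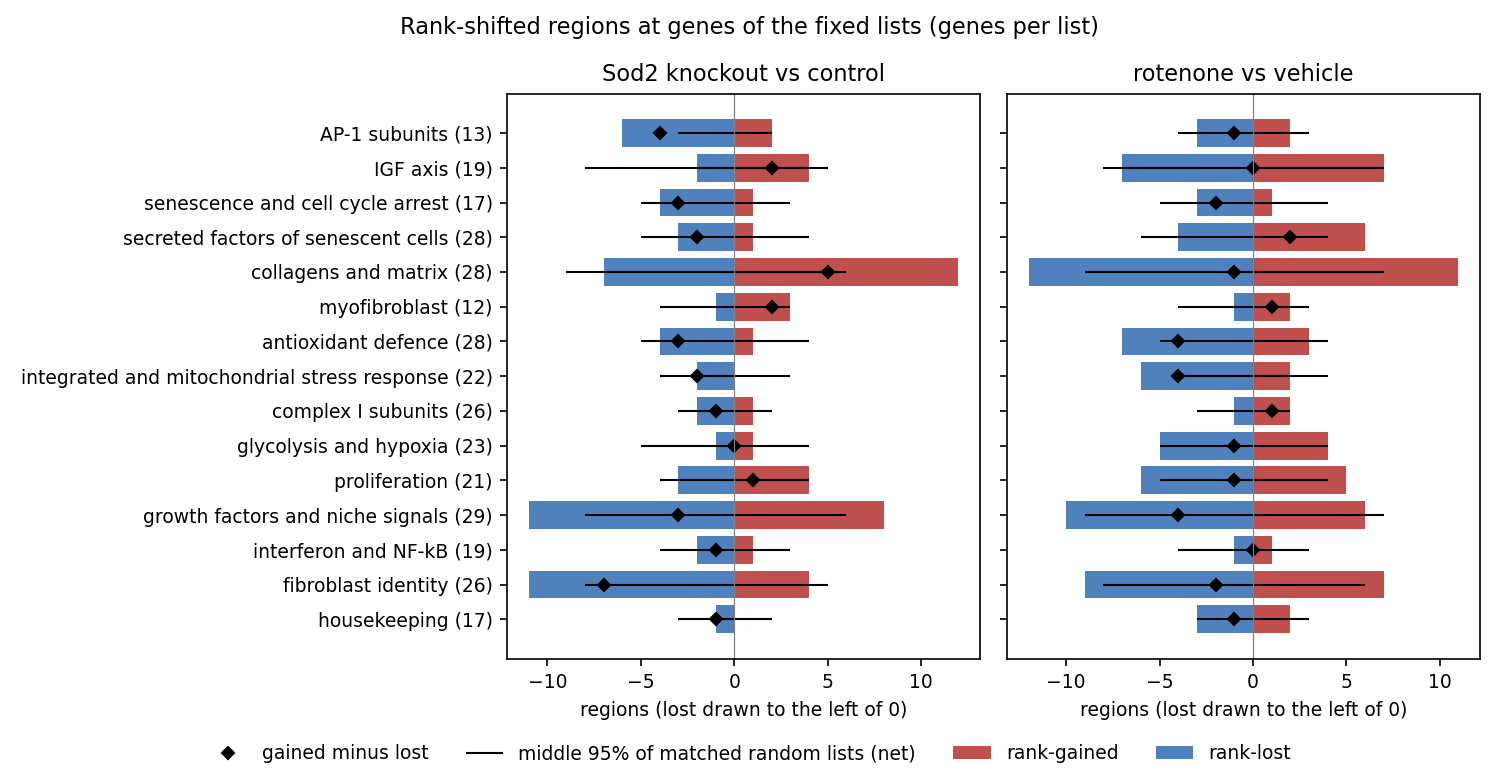
Regions gained (red, right of 0) and lost (blue, left of 0) at the genes of each fixed list (genes per list in brackets), for the knockout against control (left) and rotenone against vehicle (right). Diamonds give gained minus lost and black lines the middle 95% of that net in 10000 matched random lists; the AP-1 subunits in the knockout (-4) lie outside their line.

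In the rotenone library, strong regions assigned to Lrig3, Smad3, Col4a1 and Foxk1 were lost and regions assigned to Macrod2, Magi2 and the gene end of Thbs1 gained. Lrig3 and Ctnna3, the gene of an adherens junction catenin, lost 5 regions each, with 1 and 0 gained; 1 of those of Lrig3 lay inside the gene and 4 at 126485 to 296669 bp from it, and 3 of those of Ctnna3 lay inside. Smad3 lost 4 with 0 gained: 3 inside the gene, including chromosome 9, 63745809-63746669, and 1 at 63803203-63803664 with a fold of 8.68 in vehicle. Col4a1, which encodes a basement membrane collagen chain, lost 4 inside the gene, the strongest at chromosome 8, 11215340-11215542 (fold 7.92 in vehicle). Foxk1, a forkhead factor gene, Dad1, which encodes a subunit of the oligosaccharyltransferase, and Uck2, a uridine-cytidine kinase gene, lost 4 each with 0 gained. The best ranked of these lay inside Foxk1 and Uck2 but 124340 bp from Dad1. Tenm4 lost 4 and gained 2, and Med13l, a Mediator subunit gene, lost 4 and gained 1.

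Macrod2 gained 6 regions and lost 1, and Hnf4g, a nuclear receptor gene, gained 6, the strongest of them 506440 bp from the gene near the start of chromosome 3. Myc gained 5, between 187273 and 881227 bp from the gene, and lost 4, of which 1 (chromosome 15, 61984232-61984600) lay 925 bp from a gene end. Magi2, which encodes a membrane scaffold, gained 4 with 0 lost, Mctp2 gained 4 and lost 2, Gria1, an AMPA receptor gene, gained 3 and lost 1, and Pcsk5, a proprotein convertase gene, gained 3. Pisd (9 gained, 1 lost) and Scaf8 (7 gained) led the list and share the low fold noted for the knockout. Alkbh8, a tRNA modification gene, gained 4 regions near the start of chromosome 9, at least 258590 bp from the gene, and its best ranked had a fold of 2.16. The best ranked gained gene end peaks fell to Skint11, Aamdc, Thbs1, Adamts1 and Rmnd1. The Thbs1 peak (chromosome 2, 118127127-118127764, fold 5.04) overlapped the one gained in the knockout, and Adamts1 encodes a secreted metalloproteinase of the ADAMTS family (chromosome 16, 85793429-85793668, fold 6.83). The best ranked lost ones fell to Samd4b, C1galt1, Syt1, Syndig1 and Arfgap1. Those of Samd4b (fold 1.17) and C1galt1 (fold 1.36) were also missing from the 60000 strongest control peaks, while Syt1, a synaptotagmin gene, had a fold of 10.5 and Syndig1 of 8.64 in vehicle.

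In total 2042 regions were gained and 2413 lost in rotenone, assigned to 1749 and 2054 genes. Under the stricter definition 232 were gained and 283 lost. Gains there were 2 each at Gria1, N6amt1, Agfg2, Atpsckmt and Nfia, and losses 2 each at Kcnip4, Fam174b and Ptpn14. These counts also followed list length and the overlap rule. They were 828 and 913 regions (12 and 29 under the stricter definition) with lists of 15000, where vehicle against control gave 12 and 11 under the stricter definition. With lists of 60000 they were 9369 and 9926 (4933 and 4088), and with 50% of the peak covered 2324 and 4424 (652 and 2389).

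**Figure D4:**
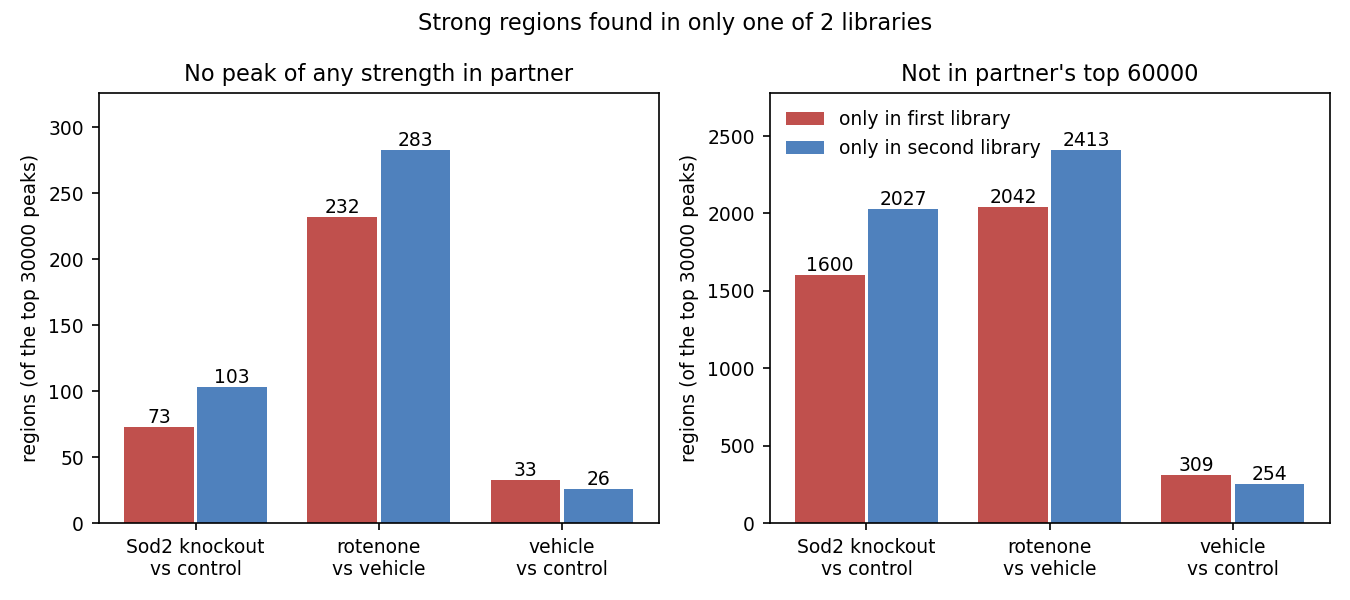
Number of regions, out of the 30000 strongest peaks, found in only 1 library of a pair: with no partner peak of any strength (left) and with no partner peak among its 60000 strongest (right). Red bars are regions only in the first library named under the bars and blue bars regions only in the second. Vehicle against control gives 33 and 26 (left) and 309 and 254 (right), fewer than either comparison, but these libraries do not differ in enrichment as the others do.

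Antioxidant defence genes in rotenone had 3 regions lost and 0 gained under the stricter definition, a net at percentile 0.095 of the random lists (middle 95%, -2 to 1). The 3 regions were assigned to Sod1, the cytosolic superoxide dismutase gene (chromosome 16, 90188744-90188817, 31981 bp from the gene, fold 6.93 in vehicle and also missing from the 60000 strongest control peaks), Gclc, which encodes a subunit of the rate-limiting enzyme of glutathione synthesis (chromosome 9, 77781577-77781661 inside the gene, fold 5.84), and Nfe2l2 (chromosome 2, 75722311-75722427, 17706 bp from the gene, fold 6.05). With lists of 60000 this net was 2. Under the second definition the list gained 3 and lost 7 (net -4, percentile 6.51), with 2 losses each at Nfe2l2 and Txnrd1 and a gain at the catalase gene Cat. Of the 28 genes, 15 had a strong gene end peak in vehicle, 18 in rotenone, 19 in control and 17 in the knockout, and 25, 25, 26 and 26 had one of any strength. Stress response genes gained 2 and lost 6 (percentile 3.49): Asns, the asparagine synthetase gene, lost 2, Eif2ak3, which encodes the kinase PERK, lost 2, and Cebpb lost 1. The rotenone peaks, like those of the knockout, were less enriched and narrower than those of the partner library.

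Collagen and matrix genes gained 11 and lost 12 regions in rotenone (near the median of the random lists), and 8 of 28 members had gains only and 5 losses only. Col1a2 lost 3 beside the 4 of Col4a1, and Postn, the periostin gene, gained 2. Growth factor and niche genes gained 6 and lost 10 (percentile 22.6), with 2 gains at Fgf10, a fibroblast growth factor gene, and 2 losses at the Wnt antagonist gene Sfrp1 in addition to those of Smad3. Fibroblast identity genes gained 7 and lost 9 (percentile 39.6); Lrig1 lost 3, of which 1 spanned 39 bp at a fold of 1.82 and was also missing from the control library, and Tbx18 lost 2. The IGF axis gained 7 and lost 7 (percentile 56.8), 2 and 3 of them inside Igf1r, and Igf1 gained 1 at a distance of 107776 bp. Secreted factors of senescent cells gained 6 and lost 4 (percentile 86.2), with 2 gains at Tnfrsf11b and 2 gains and 1 loss at Cxcl12. AP-1 genes gained 2 and lost 3 (percentile 34.7), with a loss at Jun that overlapped the one in the knockout. Senescence genes gained 1 and lost 3, at Ccng1, Cdkn1a and Hmgb1 (percentile 24.8).

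The remaining lists in rotenone lay near the centre of the random lists or short of their tails. Myofibroblast genes gained 2 and lost 1 (percentile 78.5), complex I genes 2 and 1 (percentile 81.2), glycolysis and hypoxia genes 4 and 5 (percentile 42.3), proliferation genes 5 and 6 (percentile 39.1), interferon and NF-kB genes 1 and 1 (percentile 56.4) and housekeeping genes 2 and 3 (percentile 29.4). Marker nets were -3 for melanocytes and Schwann cells (percentile 5.98, with 2 losses at Tyrp1), -2 for keratinocytes, -2 for myeloid cells, -1 for endothelial cells, adipocytes and pericytes, and 0 for lymphocytes and skeletal muscle. In the order control, knockout, vehicle and rotenone, strong gene end peaks were seen at 4, 5, 5 and 3 of 11 melanocyte and Schwann cell genes, 3, 3, 3 and 4 of 14 keratinocyte genes, 2, 2, 3 and 2 of 11 endothelial genes, 1, 2, 1 and 2 of 9 adipocyte genes, 1, 0, 1 and 1 of 9 skeletal muscle genes and 0, 0, 0 and 1 of 11 myeloid genes, and at 0 of 10 lymphocyte and 0 of 8 pericyte genes in every library. Over 23 lists and 2 comparisons, 1 net left the middle 95% under each definition, with no adjustment for the number of lists. Among so many nets some leave a 95% range by chance, so 1 outlying net under each definition does not set its list apart.

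Many of the same regions changed in both comparisons, which have separate controls. Gained regions coincided 345 times, against 76.9 for independent sets among 42457 merged strong regions, and lost regions 556 times, against 115. Regions gained in 1 comparison and lost in the other coincided 10 and 4 times, against 90.9 or more. Such a region has to be strong in vehicle and missing from the 60000 strongest control peaks, or the reverse. Only 309 and 254 regions were, so few could coincide and the low numbers are no separate support for a common change. Under the stricter definition 5 gained and 13 lost regions coincided, against 0.399 and 0.687. With lists of 60000 the sharing of gains came closer to independence, at 1091 against 739 (182 against 152 by the stricter definition), while losses coincided 2463 times against 908 (337 against 89.1). Examples lost in both were a region 17707 bp from Nfe2l2 at chromosome 2, 75722312-75722427, the Txnrd1 region at chromosome 10, 82876103-82876339, the Asns region at chromosome 6, 7676328-7676491, the Smad3 region at chromosome 9, 63745842-63746751, and the Lrig1 region at chromosome 6, 94640277-94640659. The Col1a2 region at chromosome 6, 4387128-4387166, 118471 bp from the gene, was lost in both at identical coordinates. The Thbs1 gene end, the Epas1 region at chromosome 17, 86725157-86725288, and the Jag1 region at chromosome 2, 137413495-137413810 were gained in both. Because control and vehicle resembled each other, part of the excess over independence follows from the design. The numbers for independent sets also ignore a region's rank, width and gene end position, so the excesses above may be overstated. Among strong control peaks shared with vehicle, 560 were lost from both other lists. Within strata of these properties 140 were expected, more than without strata. No such expectation was computed for gains.

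Gained and lost regions lay less often at gene ends than strong peaks as a whole, also between the libraries that differ in neither Sod2 nor rotenone. Within 1000 bp of a gene end lay 7.31% (6.14-8.69) of the regions gained in the knockout, 9.42% (8.23-10.8) of those lost, 8.13% (7.02-9.39) of those gained in rotenone and 8.62% (7.56-9.81) of those lost, against 24.4% to 24.9% of the strong peaks of each library. For vehicle against control the shares were 11.3% and 9.45%. Under the stricter definition the shares were 11.0%, 8.74%, 4.74% and 8.13%. The gained regions were farther from gene ends, at a median of 26366 bp in the knockout and 25479 bp in rotenone, against 18360 and 19158 bp for lost regions. These distances include regions inside genes, which made up 44.3% and 44.1% of gained and 52.8% and 50.7% of lost regions. Of the strong peaks, 2.01% to 2.10% lay on X in each library; of all peaks, 3.30% in control, 3.22% in vehicle, 3.81% in the knockout and 3.64% in rotenone. The Y-linked genes Ddx3y, Eif2s3y and Uty had a peak at a gene end in all 4 libraries, Kdm5d in all but vehicle and Usp9y in 0.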

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

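The settings with a minimum fold of 3, a partner peak within 250 bp, a shortened partner list and the nearest gene end, and all settings for the second definition, were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. The AP-1 motif alternatives were not run. The excess of knockout-rotenone overlap over the overlap with each own control kept its direction in every setting tried. Region counts followed list length and the overlap rule by construction; for other settings the cause was not tested. Ranking by fold enrichment and autosomes only kept every region count within 1.5 times, as did a minimum fold of 3, 250 bp and the shortened list except where named. Unknown depth limits all of these results.

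With lists of 15000, the overlap of the knockout with rotenone exceeded that with control by 6.91 percentage points and the overlap of control with vehicle exceeded that with the knockout by 10.6. By the stricter definition 5 regions were gained and 14 lost in the knockout, 12 and 29 in rotenone, 12 were only in vehicle and 11 only in control, with 0 gained and 3 lost shared; under the second, 735, 837, 828, 913, 144 and 95, with 165 and 236 shared. The gene end share was 21.4% of regions lost in the knockout and 0% of those gained in rotenone.

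With lists of 60000, the 2 excesses above were 1.83 and 11.1 points, that of rotenone with the knockout over vehicle 3.77 and that of vehicle with control over rotenone 13.0. The stricter definition gave 2839, 2004, 4933, 4088, 640 and 436 regions in the same order, with 182 and 337 shared, and the second 7256, 8423, 9369, 9926, 2445 and 2071, with 1091 and 2463 shared.

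With 50% of the peak covered, the 4 excesses were 4.39, 13.9, 5.49 and 15.2 points. The stricter definition gave 287, 1559, 652, 2389, 146 and 193 regions, with 36 gained and 443 lost shared. The second gave 3974 lost in the knockout, 4424 lost in rotenone, 548 only in vehicle and 582 only in control, with 1280 lost shared.

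Against the stronger 50% of the partner list, 155 were gained and 225 lost in the knockout and 412 and 633 in rotenone, with 15 and 42 shared. With the shortened partner list 193 were lost in the knockout and 20 losses were shared. A minimum fold of 3 left 20 only in vehicle and 14 only in control, and a distance of 250 bp 15 only in control. Within 2500 bp of a gene end lay 9.05% of regions gained and 14.5% of those lost in rotenone.

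Both list nets that lay outside the middle 95% of random lists changed direction with lists of 60000: AP-1 in the knockout, second definition, from -4 to 1, and antioxidant defence in rotenone, stricter definition, from -3 to 2. Nets inside that range also changed sign, such as collagens in the knockout, second definition, from 5 to -4 with lists of 15000 and -13 with lists of 60000. Under the stricter definition, nets in the knockout moved with lists of 60000 to -7 for proliferation, -5 for fibroblast identity, -4 for myeloid, 3 for antioxidant, 2 for stress response, melanocyte and pericyte, -2 for niche and endothelial, 1 for AP-1, secreted factors, keratinocyte and adipocyte, -1 for glycolysis, myofibroblast and muscle, and 0 with opposed changes for IGF, complex I and housekeeping genes. In rotenone they moved to -11 for proliferation, 4 for interferon, 3 for myofibroblast, 2 for keratinocyte, 1 for AP-1, adipocyte and pericyte, -1 for endothelial, lymphocyte, muscle and housekeeping, and 0 for complex I and senescence genes. With lists of 15000 nets moved to 0 for collagens, senescence and interferon in the knockout and, in rotenone, for IGF, secreted factors, collagens, antioxidant, stress response, glycolysis, niche, myeloid and melanocyte genes. Ranking by fold gave -1 for AP-1 and proliferation in the knockout and 0 for fibroblast identity in rotenone. In rotenone, genes within 50000 bp gave -1 for IGF and 0 for collagens and niche, and the nearest gene end 1 for fibroblast identity. Under the second definition, the share of gains left its 95% interval or the direction of an outlying net changed for 7 of 46 list and comparison pairs within 50000 bp, 1 by nearest gene end, 1 by fold, 7 with lists of 60000 and 30 with lists of 15000.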

Other observations

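The tests on library pairs, on loss of precision, on library quality, on shifted positions, on repeated segments and on chromosome starts were chosen after the results were seen, as were the genes named in the next paragraph; those on strata, on the vehicle share of gained regions and on distance were written before their values were computed, but after overlap counts and gene end shares had been seen.

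More than 1 region lost in both comparisons was assigned to 29 named genes. Dmbt1 led with 3, and 2 regions each were assigned to genes such as Sox2, which encodes a transcription factor of dermal papilla cells, Tcf7, an effector of Wnt signalling, Nr3c1, the glucocorticoid receptor gene, Myc, and the cytoskeletal genes Diaph3 and Epb41l3. Lrig1 and Lrig3 were also among them. Among the gains, 14 named genes had 2 shared regions each, including Efnb2, which encodes the ligand ephrin-B2, Sema3d, a secreted guidance factor gene, Tmpo, which encodes a lamina-associated protein, C1qtnf7, Magi2 and Hs6st1. Complex I genes, which encode subunits of the target of rotenone, had a strong gene end peak at 15 of 26 members in control, 18 in the knockout, 14 in vehicle and 20 in rotenone. Gene end peaks of any strength were present at 26, 26, 25 and 25 members in the same order. The strong counts thus differed by rank rather than by presence, and they include peaks assigned to neighbouring genes. Ndufs7 and Ndufb8 had a strong gene end peak in the knockout and rotenone only, while Fap, a fibroblast marker, and Prdx1, a peroxiredoxin gene, had one in control and vehicle only.

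The resemblance of the knockout and rotenone peaks may reflect a response of fibroblasts common to both mitochondrial disturbances, or a property common to both preparations. A batch that ties each library to its own partner would give the opposite pattern, since control and vehicle overlapped by 9.78 percentage points more than the mean of the pairs. It cannot give this resemblance, but a weaker batch of this kind is not excluded. Random loss of precision acting independently in each library is argued against, since the knockout overlapped rotenone by 5.26 points more than its control (1.83 with lists of 60000). Both values restate the overlaps of the pattern itself and are no separate check. Of 25780 strong control peaks that overlapped a strong vehicle peak, 560 were lost from both the knockout and the rotenone list. Within strata of rank, width and gene end position 140 were expected, a ratio of 4.00 that argues against lower enrichment acting through these properties. This count is of control peaks and not of merged regions lost against each own partner, so it differs from the 556 given in the Results. Regions gained in the knockout lay among the 60000 strongest peaks of rotenone 76.2 points more often than after a shift of 100000 bp (77.7% and 1.44%), which argues against background at random sites; the excess of 46.3 points over vehicle decides nothing, since these regions were picked as absent from control, which vehicle resembles, and background that recurs at fixed sites stays open. A difference in quality that acts alike in the knockout and rotenone libraries cannot be told apart from biology, because the lower median fold of the control and vehicle lists exceeded the higher of the other pair by 0.788, and a preparation day common to the knockout and rotenone was not tested.

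The clustered gains at Pisd, Sfi1 and Scaf8 may come from reads of repeated or copied segments. Their 30 regions had a median fold of 2.85, and 20 of them a fold under 3, which meets what that explanation predicts, although only 1 lay within 50000 bp of a peak with a −log10 p over 500. Sfi1 and Scaf8 lie near the starts of assembled chromosomes, and within 500000 bp of the first peak of a chromosome 21 regions were gained and 8 lost in the knockout, and 28 and 12 in rotenone. The lower of these ratios was 2.33, but without the regions at Pisd, Sfi1 and Scaf8 they were 2 (14 and 7) and 1.73 (19 and 11), so chance placement of the others is not excluded. Whether repeats or a true opening near the chromosome starts give these gains stays open, as no genome sequence was used here.

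Gained regions lay farther from gene ends than lost ones in both comparisons, by 1.44 times in the knockout and 1.33 times in rotenone, which argues against a chance order of single regions. A candidate explanation is more distal opening, and another is that the less enriched libraries fill their lists with weaker peaks outside genes. The share of strong peaks at gene ends, 24.4% to 24.9% in the 4 libraries, did not separate these. Strong peaks inside genes made up 53.5% in control and 53.2% in vehicle, against 51.7% in the knockout and 51.9% in rotenone, which either explanation would give. Gained regions had lower median folds (4.52 in the knockout, 4.96 in rotenone) than lost ones (5.70 and 6.04). These folds come from libraries that differ in enrichment, so they do not decide it either.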
